A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

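Total RNA of 6 cultures of wild-type S. cerevisiae was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. There were 3 DMSO cultures and 3 cultures with OGT2468, grouped and numbered by the sample titles. The deposited table holds 1 intensity per probe set and array, on a linear scale with 1 decimal. GCRMA is named in the submitters' processing notes, with a version not given in the sources used here. The deposited intensities were however not on the log2 scale that GCRMA returns and were not on a common distribution between arrays, since their medians and upper quartiles differed. How the signals were summarised or background corrected is not given in the sources used here, and no background was subtracted again.

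The planned design had taken the values to be normalized between arrays. It foresaw log2 for linear values and no further normalization. Because the arrays were not on a common distribution, this plan was left. The deposited intensities of the 8968 tested probe sets were quantile normalized across the 6 arrays, a pseudocount of 16 was added and log2 was taken. Changes are on this log2(value + 16) scale, which understates the change of dim genes, and quantile normalization removes any difference in total RNA per cell. Whether changes of the brightest genes, such as KAR2, MF(ALPHA)1 and ERG11, were compressed near the array maximum (13240 to 15820 intensity units) was not tested. The 6 alternatives chosen after seeing the data were no scaling between arrays, scaling on the hybridization controls, scaling on the upper quartile, a pseudocount of 1, a pseudocount of 64, and testing the named S. cerevisiae probe sets alone. The one with no scaling between arrays is the closest to the planned setting for a linear table. All other alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

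Probe sets were named through the platform annotation and a table of 6477 genes of the R64 assembly, used for names only. Of 10928 probe sets 5498 had 1 S. cerevisiae gene, 1747 were set aside as those of another species (1 of them with several genes), 213 were platform controls and 3470 were unnamed here. The other-species probe sets and controls were not tested as yeast genes, and the unnamed ones were tested without a name. The tested probe sets covered 5449 genes, 47 of them with more than 1 probe set, for which the brightest was used in the lists. Background on each array was the 98th percentile of the other-species probe sets, between 21.8 and 25.9 intensity units, a level chosen after seeing the data. A gene at or below it on all 3 arrays of a group has only a bound there: the mean of the bright group over the mean of, per array, the higher of the background level and the gene's own value. Among the calls, 11 higher probe sets were at background in DMSO and 7 lower ones at background in OGT2468. Probe sets that match several sequences cannot separate gene copies.

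Each probe set was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, OGT2468 against DMSO, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The 60 gene lists were tested with camera at its preset correlation of 0.01, on 1 probe set per gene, with at least 5 measured genes and adjustment over the 60 lists. With an estimated correlation camera called 0 lists, against 11 lists at an unadjusted p under 0.05, and fry, which asks whether a list's genes move on balance one way, called 17 lists. The lists held 1339 genes, of which 7 were not matched. For 6 lists, none of them called, the median, the mean and the test differed in sign. Named genes were the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, up to 4 members of each list that passed, and a fixed set of 15 genes whatever their result, plus the mating type markers. A list's SE was computed from its mean on each of the 6 arrays.

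The steps were tested on simulated data drawn from the means and spreads of the 8968 probe sets, with 200 changed. limma recovered 95.2% of 2-fold changes and 65.0% of 1.41-fold changes, and 7.5% of its calls were unchanged probe sets. In data with lists shifted by 0.3, camera recovered 50 of 50 shifted lists at the preset correlation and 48 of 50 with an estimated one, with genes simulated as independent. For arrays the precision is limited by their number, here 3 per group. Ratios of the 3' to the 5' probe sets of ACT1, SPT15 and SRB4, a measure of RNA integrity, did not separate the groups (exact two-sided permutation tests, p = 0.6, 0.2 and 0.9), nor did the hybridization controls (exact p = 0.5). These tests cannot give a p below 0.1, so a small difference stays possible. The mean log2 ratio of SPT15 was 1.52 in OGT2468 and 1.29 in DMSO.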

Results

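Transcript levels were measured on 6 Affymetrix oligonucleotide arrays in wild-type budding yeast (Saccharomyces cerevisiae) in mid-log phase. A group of 3 cultures was exposed for 3 h to 0.1 µM OGT2468, a compound known here by its code name, and 3 cultures received the solvent DMSO alone at 0.1%. The design text calls the samples biological, and each was hybridised to its own array. The arrays held 10928 probe sets, of which 5498 were assigned to 1 S. cerevisiae gene and 1747 to another species. The median intensity of the S. cerevisiae probe sets was 897, 786 and 1150 on the DMSO arrays and 842, 758 and 691 on the OGT2468 arrays (exact two-sided permutation test, p = 0.2). The arrays were therefore brought to a common distribution before testing. Between 95.6% and 97.1% of the S. cerevisiae probe sets were above background on each array.

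The comparison asked which transcripts differed after 3 h in OGT2468. In treated cells 11 of 23 measured genes of the cell wall integrity pathway and 11 of 26 of protein folding in the endoplasmic reticulum (ER) were higher, and 17 of 25 of the mating pheromone response were lower and 2 higher. Without any 1 array these counts were 10 or 11 for the cell wall, 6 or 7 for the ER and 11 to 16 lower for pheromone. As lists all 3 passed camera with a preset correlation, and none passed with an estimated one (adjusted p = 0.172 for each). PIR3, which encodes a cell wall protein, rose 11.1-fold, the largest rise measured, with a log2 change of 3.48 ± 0.12 (SE, n = 3 per group). PRM6, a pheromone-regulated gene, had the largest fall, with a log2 change of -2.45 ± 0.20 (SE, n = 3 per group). Across the genome 164 probe sets were higher and 68 were lower at a limma adjusted p under 0.05, out of 8968 tested, and 30 of the former and 22 of the latter changed at least 2-fold. With no scaling between arrays, the setting closest to the planned one, 22 were higher and 44 lower.

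Besides PIR3, the largest rises belonged to KDX1, a gene related in sequence to the cell wall kinase SLT2 (2.50 ± 0.11 on the log2 scale, SE), YPS3, a cell surface aspartic protease (2.47 ± 0.09), CRG1, a methyltransferase (2.21 ± 0.11), RTC3 (2.01 ± 0.15) and INO1, the enzyme that makes inositol phosphate (1.84 ± 0.16). SRL3 followed at 1.57, YPL088W at 1.50, PRM10 at 1.41, ULI1 at 1.40 and ICT1 at 1.31. BAG7, which encodes a GTPase-activating protein, was at background on all 3 DMSO arrays and was at least 2.15-fold higher after OGT2468 (adjusted p = 0.0307), a call lost without any 1 array other than DMSO replicate 3. The largest falls after PRM6 were those of PRM3 (-2.37 ± 0.07, SE), FIG1 (-2.27 ± 0.18), PRM2 (-2.14 ± 0.10) and PRM1 (-2.04 ± 0.14). FIG2 (-1.76) and FUS2 (-1.75) fell as well. Outside the pheromone list, YGR109W-A, an open reading frame of a Ty3 retrotransposon, fell by 1.96, and the hexose transporter gene HXT4 (-1.55), YDR124W (-1.39), IME4 (-1.32) and the glycogen phosphorylase gene GPH1 (-1.31) also fell. The call of YDR124W was lost without any 1 array other than OGT2468 replicate 2, after subtracting each array's median and with a pseudocount of 1, and with a pseudocount of 64 the changes of YDR124W and IME4 were -0.84 and -0.77. The adjusted p of these 24 genes, which were selected among calls whose groups did not overlap, lay between 0.000483 and 0.0404. Over all tested probe sets the groups did not overlap in 24.1%, against 10% by chance.

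**Figure D1:**
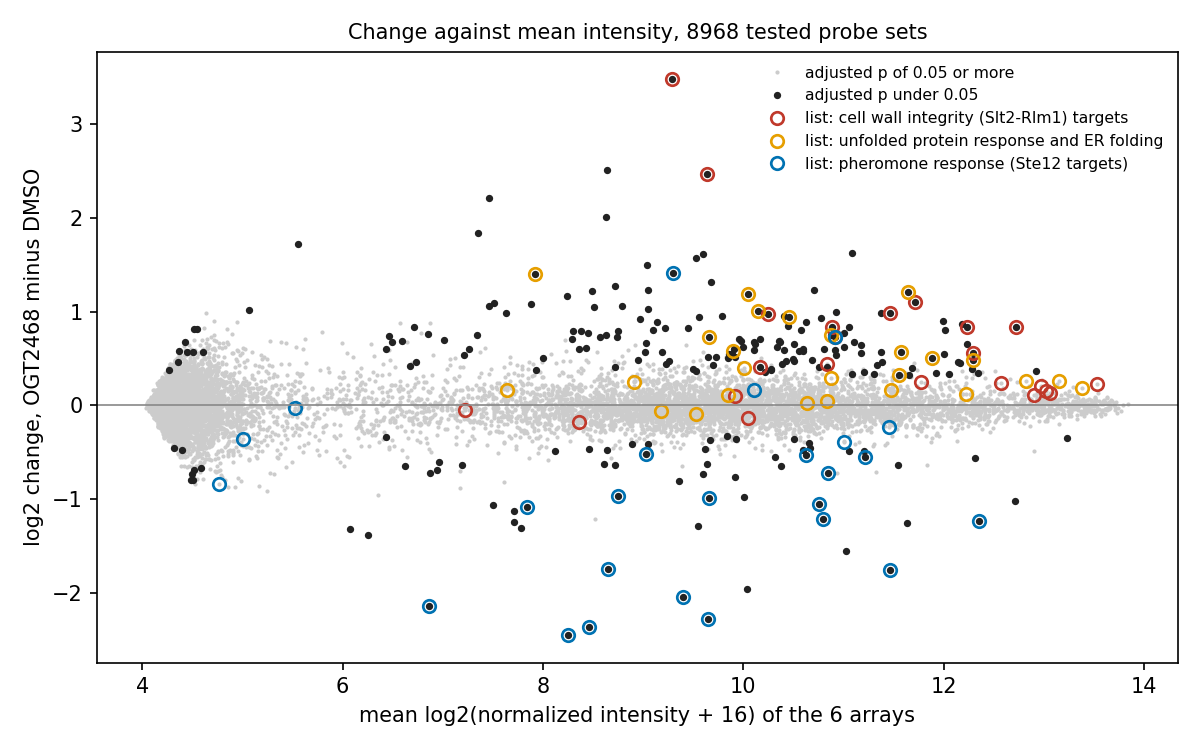
Each point is 1 of the 8968 tested probe sets, with its mean log2 intensity over the 6 arrays on the horizontal axis and its log2 change (OGT2468 minus DMSO) on the vertical axis; black points passed a limma adjusted p of 0.05, and open circles mark 3 of the gene lists. Pheromone response genes lie as low as -2.45, and cell wall integrity genes as high as 3.48.

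Of 23 measured targets of the cell wall integrity pathway, in which the kinase Slt2 activates the transcription factor Rlm1, 11 rose and none fell (17 rose when adjusted over the list alone). Without any 1 array 10 or 11 rose, with scaling on the hybridization controls 5 and with no scaling 2. The list was written with the name MLP1, which KDX1 has also carried, but KDX1 (2.50) was not among the genes counted. Names were matched by present symbol first, so another gene now called MLP1 may be among the 23. The mean log2 change of the list was 0.64 ± 0.02 (SE, 3 arrays per group; camera adjusted p = 3.69e-14, and adjusted p = 0.172 with an estimated correlation). The kinase gene SLT2 itself rose from 11.17 ± 0.10 to 12.26 ± 0.06 (log2 intensity, SD, n = 3), a change of 1.10, and GSC2, also called FKS2 and encoding a subunit of glucan synthase, rose by 0.98. The calcineurin list, genes controlled by the transcription factor Crz1, shares GSC2 with it. Of 15 measured members of that list 4 rose and none fell (8 rose when adjusted over the list alone), namely YPS1 (0.99), GSC2, CMK2 (0.81) and KRE6 (0.34). The count was 3 without DMSO replicate 2 or OGT2468 replicate 1, 2 without any other 1 array, 2 with control scaling and 0 with no scaling. Its mean change was 0.39 ± 0.04 (camera adjusted p = 3.66e-07, and adjusted p = 0.172 with an estimated correlation). Of 18 measured osmotic stress genes controlled by the kinase Hog1, 5 rose and none fell (9 rose when adjusted over the list alone), and the mean change was 0.33 ± 0.05 (median -0.05 with no scaling between arrays; camera adjusted p = 7.55e-05, and adjusted p = 0.172 with an estimated correlation). Among them were RTC3, the glycerol synthesis gene GPD1 (0.89), HSP12 (0.88) and GRE2 (0.70). The count of 5 fell to 1 without DMSO replicate 1 or 3, 2 without OGT2468 replicate 3, 3 without OGT2468 replicate 1 or 2, and 1 with no scaling or control scaling, and it was 4 without DMSO replicate 2. The call of GPD1 was lost in 5 of the 6 fits without 1 array, that of HSP12 in 3 and that of GRE2 in 6.

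In the list of the unfolded protein response and ER folding, 11 of 26 measured genes rose and none fell (18 rose when adjusted over the list alone), but 7 rose without DMSO replicate 1, 6 without any other 1 array, 5 with control scaling and 2 with no scaling. The mean change was 0.45 ± 0.02 (SE; camera adjusted p = 3.69e-14, and adjusted p = 0.172 with an estimated correlation). ULI1 rose by 1.40, ERO1, the oxidase that drives disulfide bond formation, by 1.21, SIL1, a nucleotide exchange factor of the ER chaperone Kar2, by 1.19, and the protein disulfide isomerase gene MPD1 by 1.01. KAR2 itself had a log2 change of 0.18 ± 0.05 and did not pass over all probe sets tested (limma adjusted p = 0.163). KAR2 was among the 18 genes that rose when adjusted over the list alone. Its level, 13.29 in DMSO and 13.47 in OGT2468 (log2 intensity), was near the array maximum, where compression of the change was not tested. Of 39 measured genes of N- and O-glycosylation, 4 rose and none fell (12 rose and 1 fell when adjusted over the list alone). These were the protein O-mannosyltransferase genes PMT3 (0.69) and PMT1 (0.47) and the mannosyltransferase genes OCH1 (0.68) and KTR1 (0.35). The count was 2 without DMSO replicate 2 or OGT2468 replicate 1, 1 without any other 1 array, and 0 with no scaling or control scaling. The mean change of the list was 0.15 ± 0.02, with a median of -0.14 with no scaling and -0.04 with control scaling (camera adjusted p = 1.53e-05, and adjusted p = 0.172 with an estimated correlation). In the list of vesicle transport from the ER to the Golgi, 1 of 30 measured genes rose, the cargo receptor gene ERV29 (0.40), a call lost without any 1 array, and 2 rose when adjusted over the list alone. SEC28 (0.35), SEC16 (0.27) and ERV25 (0.23) did not pass. The mean change was 0.11 ± 0.02, with a median of -0.15 with no scaling and -0.05 with control scaling (camera adjusted p = 0.000391, and adjusted p = 0.228 with an estimated correlation). The camera call of this list was lost under both of these scalings.

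**Figure D2:**
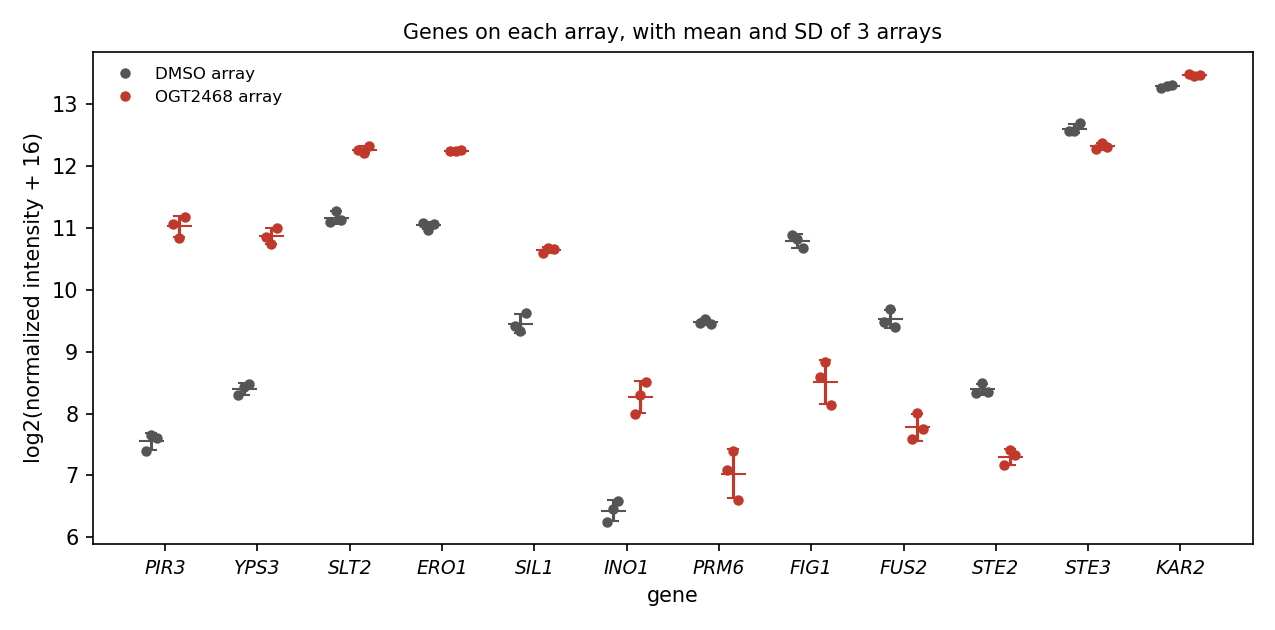
The vertical axis gives log2(normalized intensity + 16), with 1 point per array, a horizontal line for the mean and bars for the SD of 3 arrays, for 12 genes on the horizontal axis; levels of different genes are not comparable with each other. PIR3 rose from 7.55 to 11.03 and PRM6 fell from 9.48 to 7.03, whereas the changes of STE3 and KAR2, at -0.29 and 0.18, did not pass over all probe sets tested.

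Of 25 measured targets of the pheromone response, genes activated by the transcription factor Ste12 during mating, 17 fell and 2 rose (19 fell and 2 rose when adjusted over the list alone), and without 1 array between 11 (without DMSO replicate 3) and 16 (without OGT2468 replicate 2) fell. The mean change was -0.93 ± 0.05 (SE; camera adjusted p = 9.31e-14, and adjusted p = 0.172 with an estimated correlation). PRM1 and FUS2 act in the fusion of mating cells, PRM3 acts in the fusion of their nuclei, and FIG1 takes part in calcium entry during mating. The 2 members that rose were PRM10 and PRM5 (0.73), and PRM5, named after its value was seen, is also on the cell wall integrity list. The labels give no mating type. Markers of the a mating type moved with this list: of 7 measured genes 3 fell (4 when adjusted over the list alone), with a mean change of -0.61 ± 0.08 (camera adjusted p = 0.000841, and adjusted p = 0.172 with an estimated correlation). STE2, the receptor for alpha factor, fell from 8.39 ± 0.09 to 7.30 ± 0.13 (log2 intensity, SD, n = 3), and MFA2 (-1.06) and STE6 (-0.61) fell, in calls lost in 3 and 5 of the 6 fits without 1 array. The count of 3 was 1 without DMSO replicate 3, OGT2468 replicate 1 or OGT2468 replicate 3, and 2 without DMSO replicate 2. STE2 is also on the pheromone list. The median change of the list depended on the pseudocount, at -0.61 with 16, -0.91 with 1 and -0.31 with 64. ASG7 and AGA2 were at background on all 3 OGT2468 arrays, and MFA1 (-0.28) and BAR1 (-0.03) did not pass.

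Of 5 measured markers of the alpha mating type, 2 fell (4 when adjusted over the list alone), MF(ALPHA)2 (-0.35) and HMLALPHA1 (-0.46), whose sequence is also carried by the alpha form of the mating-type locus and cannot be assigned to 1 copy. Both calls were lost without any 1 array. Without OGT2468 replicate 2 the count was 1, from SAG1, and without any other 1 array it was 0. With all 6 arrays SAG1 (-0.49), STE3 (-0.29) and MF(ALPHA)1 (-0.08) did not pass. The mean change was -0.33 ± 0.04 (camera adjusted p = 0.00115, and adjusted p = 0.256 with an estimated correlation). The camera call of this list was lost with no scaling and with control scaling. Of 11 measured haploid-specific genes 3 fell (4 when adjusted over the list alone), SST2 (-0.72), FAR1 (-0.55) and FUS3 (-0.53), and the mean change was -0.22 ± 0.02 (camera adjusted p = 0.0182, and adjusted p = 0.228 with an estimated correlation). Without DMSO replicate 1 or 3 none fell, 1 fell without DMSO replicate 2 or OGT2468 replicate 3, and 2 without OGT2468 replicate 1 or 2. The 3 that fell are also on the pheromone list, which shares 4 measured genes with the haploid list and 4 with the a list. GPA1 (-0.23), STE4 (-0.21), HO (0.04), RME1 (-0.04) and STE5 (0.02) did not pass.

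The list of inositol and phospholipid synthesis rose through INO1 and OPI3 (0.62), a phospholipid methyltransferase gene, 2 of its 17 measured genes (also 2 when adjusted over the list alone), with a mean change of 0.21 ± 0.02 and a median of -0.18 with no scaling and -0.08 with control scaling (camera adjusted p = 0.0182, and adjusted p = 0.228 with an estimated correlation). That call was lost without OGT2468 replicate 2 (adjusted p = 0.0722). Of 33 measured G1/S cell cycle genes 2 rose (7 when adjusted over the list alone), the repressor gene YOX1 (0.71) and SVS1 (0.45), and the mean change was 0.13 ± 0.03, with a median of -0.15 with no scaling and -0.06 with control scaling (camera adjusted p = 0.00105, and adjusted p = 0.336 with an estimated correlation). Without any 1 array other than OGT2468 replicate 2 the count was 1. The G1 cyclin gene PCL1 (0.51) did not pass. In the list of autophagy and vacuolar proteases, PRB1, a vacuolar protease gene, rose by 0.80 and APE1, a vacuolar aminopeptidase gene, fell by 0.74, out of 23 measured genes (5 rose and 1 fell when adjusted over the list alone). The call of PRB1 was lost without DMSO replicate 1 or 3, and that of APE1 in 4 of the 6 fits without 1 array, the exceptions being those without DMSO replicate 1 and OGT2468 replicate 2. The mean change was 0.11 ± 0.05, with a median of -0.14 with no scaling and -0.05 with control scaling (camera adjusted p = 0.0182, and adjusted p = 0.641 with an estimated correlation). The list means of the 2 groups of arrays overlapped (exact two-sided permutation test, p = 0.2). This call was lost without DMSO replicate 1 (adjusted p = 0.127) and without OGT2468 replicate 2 (adjusted p = 0.0728). The camera calls of the autophagy and G1/S lists were also lost with no scaling and with control scaling.

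The remaining 2 lists that passed shifted downwards by small amounts over many genes. The mean change of 47 measured genes of the mitochondrial ribosome was -0.20 ± 0.02 (SE; camera adjusted p = 1.27e-09, and adjusted p = 0.228 with an estimated correlation). MRPL13 (-0.40) was the 1 member that fell over all genes tested, a call lost without any 1 array, and 20 fell when adjusted over the list alone. Over 56 measured genes of ribosome biogenesis the mean change was -0.12 ± 0.04 (camera adjusted p = 0.000132, and adjusted p = 0.641 with an estimated correlation). None of them passed in limma, alone or adjusted over the list alone, and MAK16 (-0.43), NOC3 (-0.27), KRR1 (-0.27) and RRP5 (-0.24) were the members with the lowest p.

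**Figure D3:**
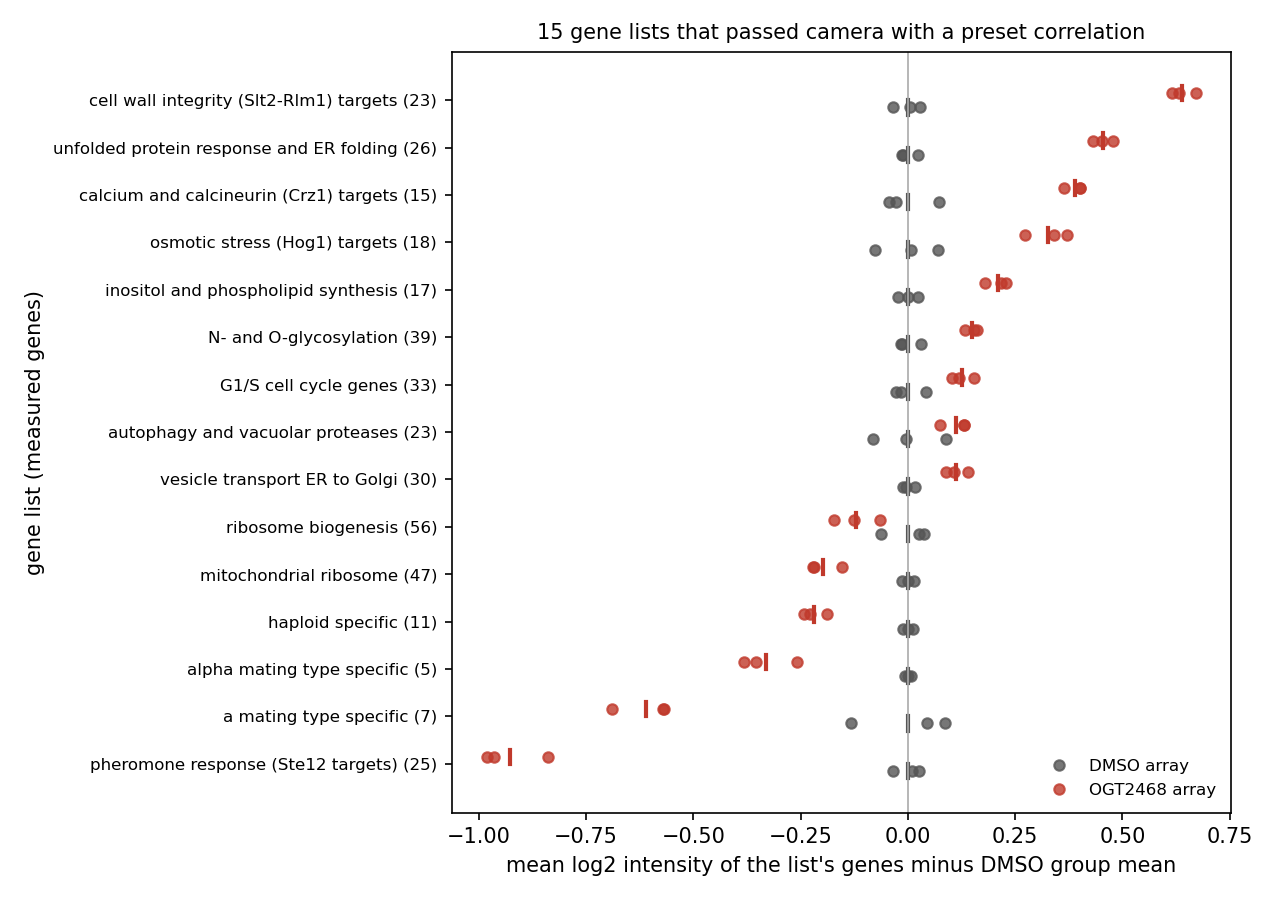
Each row is 1 of the 15 lists that passed camera with a preset correlation, with its number of measured genes; points are arrays, the horizontal axis is the mean log2 intensity of the list's genes minus the mean of the DMSO group, and short lines are group means. The treated arrays lie around 0.64 for cell wall integrity and around -0.93 for the pheromone response, while in the list of autophagy and vacuolar proteases, with a mean change of 0.11, 1 treated array lies within the range of the DMSO arrays. With no scaling between arrays 6 of the 9 higher lists had a median below 0.

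The other 45 of the 60 lists did not pass. Among the targets of the drug resistance factors Pdr1 and Pdr3, 4 of 24 measured genes rose (YPL088W, ICT1, GRE2 and RTA1, the last named after its value was seen; 5 when adjusted over the list alone), with a mean change of 0.16 ± 0.03 and a camera adjusted p of 0.0818. The count was 3 without OGT2468 replicate 1 and 2 without any other 1 array. The drug exporter genes PDR5 (0.23), YOR1 (0.15) and SNQ2 (-0.04) did not pass. Of 24 measured genes of ergosterol synthesis none passed in limma over all genes tested, 2 fell when adjusted over the list alone, and the camera adjusted p was 0.945. ERG11 (0.01), ERG3 (-0.08) and HMG1 (-0.08) did not pass, nor did the fatty acid desaturase gene OLE1 (-0.06), the DNA damage gene RNR3 (-0.35), the cytochrome gene CYC1 (0.08) or the iron uptake gene FET3 (-0.38). The camera adjusted p was 0.934 for cytosolic ribosomal proteins, 0.663 for heat shock targets and 0.408 for proteasome genes, with mean changes of -0.01, -0.03 and 0.02.

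Differences were tested with limma on 3 arrays per group and lists with camera, and an exact test of 3 against 3 cannot give a two-sided p below 0.1. Of all calls 70.7% were higher. With no scaling between arrays, the setting closest to the planned one, 22 probe sets were higher and 44 lower (33.3% higher). With scaling on the hybridization controls 45 were higher and 55 lower (45.0% higher). Under these 2 settings the median change of all named genes moved from -0.02 to -0.27 and -0.18. With no scaling the list medians of cell wall integrity and ER folding were 0.13 and 0.07, in place of 0.41 and 0.31, and 6 of the 9 higher lists had a median below 0 (5 with scaling on the hybridization controls), so their rise was one relative to the other genes. Without any 1 array the counts fell to between 61 and 91 higher and 28 and 40 lower. The calls of PMT1, KTR1, KRE6, ERV29, SVS1, GRE2, FAR1, MF(ALPHA)2, HMLALPHA1 and MRPL13 were lost without any 1 of the 6 arrays, and those of SLT2, GSC2, SIL1, MPD1 and YPS1 were lost with no scaling between arrays. Of 54 genes named here by the rule and called, between 32 (without DMSO replicate 3) and 40 (without OGT2468 replicate 2) kept their call without 1 array, among them PIR3, YPS3, KDX1, ERO1, PRM3, PRM6, FIG1 and STE2 in each case, while FIG2 lost it without DMSO replicate 3 and without OGT2468 replicate 3. With the replicate number as a block 25 of these 54 genes kept their call, and 27 probe sets were higher and 14 lower.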

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

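Of the alternatives below, no scaling, scaling on the controls or the upper quartile, the other pseudocounts and the restriction to named probe sets were chosen after seeing the data. No scaling is the closest to the planned setting for a linear table. Quantile normalization and a pseudocount of 16, planned as alternatives, became the setting of the report. No call of the report had the opposite sign under any alternative that refitted all probe sets, and relative to other genes no list that passed changed direction in camera. The list medians themselves fell below 0 for 6 of the 9 higher lists with no scaling (inositol, glycosylation, osmotic stress, autophagy, G1/S and ER to Golgi) and for these except osmotic stress with control scaling. Counts of probe sets moved by over 1.5 times in many cases. Higher and lower calls numbered 101 and 41 after subtracting each array's median, 22 and 44 with no scaling between arrays, and 356 and 240 with trend and robust moderation. They numbered 292 and 187 with a pseudocount of 64, 326 and 203 with named S. cerevisiae probe sets only, and 380 and 257 without the dimmest 50% of probe sets. With scaling on the hybridization controls 45 were higher, and without the dimmest 25% 115 were lower. A threshold of 0.01 gave 56 and 21 calls and a minimum of 2-fold gave 30 and 22. Removing dim or unnamed probe sets leaves fewer tests and a prior spread estimated from fewer probe sets. What moved the counts was not tested, nor was it for the scalings. Without 1 array, which leaves fewer samples, there were 61 to 91 higher and 28 to 40 lower calls: 66 and 32 without DMSO replicate 1, 86 and 39 without DMSO replicate 2, 61 and 28 without DMSO replicate 3, 88 and 40 without OGT2468 replicate 1, 91 and 40 without OGT2468 replicate 2, and 71 and 29 without OGT2468 replicate 3. Of the report's calls 54 higher and 20 lower ones were kept in all 6 of these fits.

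With the replicate number as a block (replicate block) there were 27 higher and 14 lower calls, all among the report's, and 9 and 6 lists. Deviations of arrays with the same number correlated at 0.19, 0.14 and 0.06, against -0.15 to 0.01 for arrays with different numbers. Not all of the former were above the threshold of 0.1, so the numbers were not taken to pair the samples. Each array correlated best with its own number, so a pairing stays possible. List counts changed by over 1.5 times in 1 case: camera with an estimated correlation called 0 higher and 0 lower (lowest adjusted p = 0.172). The G1/S, alpha mating type and ER to Golgi lists were lost with no scaling and with control scaling, autophagy also there, and the inositol list without the dimmest 50% (adjusted p = 0.121). Ribosome biogenesis (adjusted p = 0.116) and autophagy (adjusted p = 0.159) were not called by fry. Signals near background limit the a mating type markers and BAG7.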

Other observations

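The genes in this paragraph other than YGR109W-A and HXT4 were chosen after their values were seen. Open reading frames of Ty3, a retrotransposon, were lower after OGT2468: YGR109W-A at -1.96, YGR109W-B at -1.26 and YIL082W-A at -1.02, although probe sets cannot separate Ty3 copies, and the call of YGR109W-B was lost without any 1 array other than OGT2468 replicate 3. Of 14 measured genes of filamentous growth and flocculation 3 fell, FLO11 (-1.25), a cell surface adhesin gene, PGU1 (-0.72), a pectin-degrading enzyme gene, and TEC1 (-0.63), a transcription factor that binds with Ste12, while DIA1 rose (1.03). The calls of FLO11 and TEC1 were lost without any 1 array and that of PGU1 in 4 of the 6 such fits. That list did not pass (camera adjusted p = 0.35). Among 19 measured genes of the hexose transport list, which holds regulators as well as transporters, HXT1 (0.98) and HXT5 (0.60) rose and HXT4 fell by 1.55. Leaving out 1 array ended the call of HXT1 in 5 of 6 fits and that of HXT5 in 2 (without DMSO replicate 1 or 3), and the list did not pass (camera adjusted p = 0.934). In the list of glycosylphosphatidylinositol (GPI) anchor synthesis, MCD4 (0.93) and GWT1 (0.68) rose out of 24 measured genes, with a camera adjusted p of 0.228. Of the iron uptake genes on the Aft1 list 2 of 27 fell, FIT2 (-1.13) and FRE3 (-0.33), in calls lost without any 1 array, with a camera adjusted p of 0.318.

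The tests of array brightness, of fewer a cells, of a bias with intensity and of genes varying together were chosen after the result was seen; the test of single arrays was not. For the fall of the pheromone genes, the list median was -0.95 or lower under both other scalings that remove a difference in array brightness. The main setting removes that difference too, so this outcome was largely fixed beforehand. On genes of the list varying together the tests differed: fry called the list (adjusted p = 0.000439) and camera with an estimated correlation did not (adjusted p = 0.172). Between replicate arrays the list mean had an SD of 0.03 in DMSO and 0.08 in OGT2468, beside a change of -0.93. These values argue against such variation as the source of the fall. In DMSO the a-specific genes AGA2, ASG7, BAR1 and MFA1 were near background, at 5.19 to 5.67 (log2 intensity), and STE2, the highest, was at 8.39. The alpha markers were at 10.89 to 13.44, so any a cells were probably a minor part of the cultures. A mixed culture with fewer a cells after treatment remains a candidate explanation. Of the 3 a-specific genes outside the pheromone list and above background on all DMSO arrays 2 fell, MFA2 and STE6, and MFA1, near background, decides nothing. A gene outside this hand-written list can still respond to pheromone, so these falls cannot tell fewer a cells from a lower activity of the pheromone pathway. The alpha markers MF(ALPHA)2 (-0.35) and HMLALPHA1 (-0.46) fell too, and SAG1 (-0.49) and STE3 (-0.29), which did not pass, were below 0 in every setting, unlike MF(ALPHA)1 (-0.08). Leaving out 1 array at a time ended the calls of MF(ALPHA)2 and HMLALPHA1 in 6 of 6 fits, of STE6 in 5, of MFA2 in 3 and of STE2 in 0. A larger share of alpha cells would raise the alpha markers, whereas diploid cells or less a-factor would lower them. Diploid cells would also lower haploid-specific genes outside the pheromone list. Of these HO (0.04 ± 0.06, SE), RME1 (-0.04 ± 0.06), STE5 (0.02 ± 0.06) and NEJ1 (0.11 ± 0.08) hardly moved. STE18 (-0.11 ± 0.09), AXL1 (-0.19 ± 0.12) and STE4 (-0.21 ± 0.06) were lower without passing. Together they argue against diploid cells as the whole source of the fall. The share of a cells stays open, and a lower activity of the pheromone pathway after OGT2468 stays open beside it, as untested.

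The rise of cell wall integrity and ER folding genes was tested against brightness, single arrays and genes varying together. Relative to all named genes the lower of the 2 list medians was 0.32 at its lowest without each array in turn, above the 0.15 set as the bound, which argues against a single array as the source of the shift, although the ER genes called fell from 11 to 6 or 7 in these fits. With nothing subtracted the lower list median was 0.32 at its lowest under both other scalings that remove a difference in brightness. It was 0.07 with no scaling, beside -0.27 over all named genes. Removing that difference thus did not remove the shift, but the main setting removes it too, so this outcome was largely fixed beforehand. On genes of the lists varying together the tests differed: fry called both lists (adjusted p = 0.000439), and camera with an estimated correlation called neither (adjusted p = 0.172). Between replicate arrays the mean of the cell wall list had an SD of 0.03 in each group, beside a change of 0.64. For the ER list the SD was 0.02 in each group, beside a change of 0.45. These values argue against such variation as the source of the rise, with 3 arrays per group. A response of these pathways to OGT2468 stays open, as a hypothesis.

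The downward shift of the mitochondrial ribosome was small, with a median of -0.19. Random lists matched on mean intensity had medians down to -0.075 at the lower end of their central 95%, which argues against a bias with intensity. Under both other scalings that remove a difference in brightness the list median nearest to 0 was -0.20. The main setting removes that difference too, so this outcome was largely fixed beforehand. On genes of the list varying together between arrays the tests differed: camera with the correlation estimated from the list did not call it (adjusted p = 0.228), whereas fry, which asks for a change without comparing with other genes, did (adjusted p = 0.00549). Between replicate arrays the list mean had an SD of 0.01 in DMSO and 0.04 in OGT2468, beside a change of -0.20. These values argue against such variation as the source of the shift, with 3 arrays per group. An effect of OGT2468 on these genes stays open, as untested.

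Splitting the same 6 arrays into 3 and 3 in all 10 ways gave as many called probe sets in 1 split, the real one, with 232 calls against at most 0 in any other. For gene lists 1 split, the real one, had as many, with 15 called against at most 13 in another split. With 10 splits a share under 0.05 cannot be reached. The preset correlation of camera therefore also called lists in splits that mix treated and untreated arrays. Such splits still hold part of the difference between the groups, and the rest of it adds to their spread. Their counts are therefore not those expected without a treatment difference.

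The 1747 other-species probe sets gave 0 calls in limma (65 higher and 54 lower at an unadjusted p under 0.05), and the 213 platform controls also gave 0 (10 higher and 16 lower).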
